A study of Mus musculus with 12 samples.

How the data were processed

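Transcript levels were measured by RNA sequencing of total RNA from Ocy454 cells, in 12 samples that form 4 groups of 3 by genotype and treatment, as the labels give them. Per the submitters' processing notes, reads were checked with FastQC 0.11.5, transcripts were quantified with Salmon against an index of the mouse genome build GRCm38, and groups were compared with DESeq2. The Salmon and DESeq2 versions, the annotation release and the way transcripts were summed to genes are not given in the sources used here.

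The authors deposited 3 tables, each holding 1 group beside the vehicle libraries. The per-library signal in the deposited tables is a normalised estimated count: in every library 100% of values were whole multiples of 1 factor within a tolerance of 0.02 counts, so the authors divided whole estimated counts by 1 size factor per library. The deposited log2 fold changes are the authors' log2 ratios of the group to the vehicle, and differed from the log2 ratio of group means by at most 0.0097. The deposited p-value column holds the authors' adjusted p-values, and the deposited -log10 column is minus log10 of these and was not used here. The lowest estimated count of a listed gene in any library was 11, so genes counted lower in any library of a table are not in it.

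Each table was analysed with its own scaling, because the same vehicle libraries differed between tables by a factor per gene, with an SD over genes of 0.12 log2 units between the PTH and PF431396 tables, 0.07 between PTH and KO and 0.12 between PF431396 and KO. Of the genes and unnamed rows listed, 8, 6 and 8 in the KO, PF431396 and PTH tables named no gene and were left out, with at most 0.0249% of a library's estimated counts. The PTH table also held 1036792 rows with no values. The values of PF431396 replicates 1 and 3 were identical, so they were counted once. Gene positions came from the GENCODE annotation of GRCm38, which matched 11783 of 12003 genes (98.2%).

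Groups were compared with limma 3.58.1 in R 4.3.3 (trend and robust variance, with statmod 1.5.0) on log2 of the value plus 1, with 2 groups in each fit, no covariate and Benjamini-Hochberg adjustment over all genes tested. Genes with adjusted p below 0.05 and a log2 fold change of at least 1 in either direction were counted as changed. These p-values measure the spread between libraries, which may be technical, since the labels do not say whether the libraries come from separate cultures. Pde8a was also compared with an exact permutation test. Direct differences between groups were tested as contrasts of vehicle-relative values over the 11095 genes in all 3 tables. A test on the recovered estimated counts was not run. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

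On simulated data with 200 changed genes, limma called 73% and 78% of genes changed by log2 1.5 and 2 in the PTH design. The shares were 31% and 43% in the PF431396 design and 67% and 91% in the KO design. False calls numbered 3, 0 and 2. The simulations drew noise independently for each gene. They also changed fewer genes than the 456, 3005 and 1328 that passed in the real comparisons. The simulated shares and false calls therefore do not give those of the real data.

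The thresholds, the gene lists and the rule for named genes were fixed before the data were examined. The 26 lists hold 429 genes: cAMP/CREB targets, PTH-responsive genes, osteocyte markers, osteoblast and bone matrix genes, phosphodiesterases, cAMP pathway components, focal adhesion and integrins, YAP/TAZ-TEAD targets, SRF/MRTF and contractile genes, Wnt/beta-catenin, BMP and TGF-beta, proliferation, p53 and stress arrest, interferon-stimulated, inflammatory and NF-kB, matrix remodelling, cholesterol synthesis, unfolded protein and amino-acid stress, hypoxia and glycolysis, circadian clock, ERK-pathway feedback, and adipocyte, chondrocyte, macrophage and osteoclast, endothelial and muscle markers. Members are counted over all genes tested and adjusted over the list alone. The 22 lists with at least 3 measured members were set against the other genes with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 66 tests, and fry tested whether each moved on balance 1 way.

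Named genes are Pde8a, then among changed genes with a mean level of at least 100 and a named symbol the 10 largest increases and 10 largest decreases, then up to 4 members of each list with the smallest adjusted p, and Sost, Tnfsf11, Mef2c, Crem, Nr4a2, Pth1r, Dmp1, Ptk2, Ptk2b and Pde8b. For overlaps they are the 6 genes changed in the same direction in all 3 comparisons ranked by their smallest change in any comparison, and 6 changed in opposite directions. Overlaps were set against 50 simulations of unchanged groups that share the vehicle libraries, and gene families against 10000 random lists matched on mean level. The alternatives tried were other thresholds, a minimum mean level, upper-quartile scaling, other pseudocounts, all groups in 1 fit, a replicate block and each library left out. Scaling every library to the same total, the authors' deposited calls, the 3 PF431396 columns taken as 3 libraries, and overlaps without each library were added after the data were seen.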

Results

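RNA sequencing measured transcript levels in Ocy454 cells, an immortalised mouse line with features of osteocytes, the cells embedded in bone matrix that sense load and parathyroid hormone (PTH). The 12 samples fell into 4 groups of 3: wild-type cells with vehicle, wild-type cells with PTH, wild-type cells with PF431396, and cells with a knockout (KO) of Pde8a, which encodes a cAMP-degrading phosphodiesterase. PF431396 is a small-molecule inhibitor of focal adhesion kinase (FAK, encoded by Ptk2) and of its relative PYK2 (Ptk2b). The labels of the values name DMSO for the vehicle libraries and for the KO libraries. They do not say whether the PTH or PF431396 cells also received it. Doses and treatment times are not given in the sources used here. The 3 vehicle libraries served as the reference in each comparison. Each library held between 27715795 and 35752975 estimated counts in the listed genes, and the lowest estimated count of a listed gene in any library was 11. Levels are normalised estimated counts (mean ± SD), changes are log2 fold changes against vehicle with their SE, and p-values are from limma, adjusted over all genes tested in that comparison.

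The values of PF431396 replicates 1 and 3 were identical in all 11490 genes and unnamed rows of that table, so they were counted as 1 library and the PF431396 group had n = 2. Vehicle library 1 stood apart from the other vehicle libraries. Across genes of the KO table, which are not independent replicates, its log2 values had r = 0.947 and 0.945 with vehicle libraries 2 and 3, which had r = 0.992 with each other. In the PTH table the spread (SD) over genes of its log2 deviation from the mean of libraries 2 and 3 was 0.72, against 0.27 between libraries 2 and 3. Some bone genes were low in it. Ibsp, which encodes bone sialoprotein, was at 6353 normalised estimated counts against 28596 and 31584 in libraries 2 and 3. The PTH receptor gene Pth1r was at 1204 against 10083 and 11261. The share of counts from the 13 mitochondrial protein-coding genes was 3.83% to 5.19% in the vehicle libraries, 4.50% to 4.81% under PTH, 3.61% to 4.31% in the KO, and at least 11.8% in both PF431396 libraries.

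PTH acts on bone cells through a receptor that raises cAMP, and the comparison of PTH with vehicle asks which transcripts follow in these cells. Rgs2, which encodes a regulator of G-protein signalling, rose from 61.4 ± 31.2 to 3545 ± 156 normalised estimated counts (n = 3 in each group; log2 fold change 5.97 ± 0.39, adjusted p = 0.000445). The orphan nuclear receptor genes Nr4a2 and Nr4a3, induced early by cAMP in many cells, rose by log2 fold changes of 4.99 ± 0.30 and 4.18 ± 0.17, and the vitamin D receptor gene Vdr rose from 715 ± 226 to 12238 ± 1729, a log2 fold change of 4.14 ± 0.25 (adjusted p = 0.000343). Pde8a itself rose, from 2760 ± 270 to 6589 ± 114 (log2 fold change 1.26 ± 0.11, adjusted p = 0.00101), in each of the 3 PTH libraries. The cAMP phosphodiesterase gene Pde4b rose further, from 487 ± 49.2 to 6673 ± 754 (log2 fold change 3.77 ± 0.13, adjusted p = 8.26e-05). In GRCm38 coordinates Rgs2 lies on the minus strand of chromosome 1 from 143999338 to 144004161, and Pde8a on the plus strand of chromosome 7 from 81213596 to 81334533.

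The other large increases under PTH were Il1rl1, the receptor gene for interleukin 33, at a log2 fold change of 4.82 ± 0.29, and the transcription factor gene Glis1 (4.50 ± 0.25). The Wnt ligand gene Wnt4 rose by 4.49 ± 0.34, and S1pr1, which encodes a receptor for sphingosine 1-phosphate, by 4.00 ± 0.38. The amino acid transporter gene Slc43a2 rose by 3.97 ± 0.52, a call that ended without PTH library 3 (3.95, limma adjusted p = 0.0501). A run that leaves out a library has fewer libraries, so a call can end with little change in the fold change. Among the decreases, the log2 fold change was -2.17 ± 0.14 for Foxd1, a forkhead transcription factor gene, -2.01 ± 0.20 for Cdk5r1, the activator of the kinase Cdk5, -1.94 ± 0.24 for Jph2, -1.90 ± 0.13 for the Wnt receptor gene Fzd5 and -1.88 ± 0.12 for the kinesin gene Kif21b. The remaining large decreases were Tfcp2l1 (-2.27 ± 0.45), Apobr (-2.14 ± 0.48), Trib3 (-2.10 ± 0.42), Pla2g4b (-1.93 ± 0.38) and Extl1 (-1.91 ± 0.37). Those 5 calls ended without any 1 of the 3 PTH libraries, at log2 fold changes between -2.30 and -1.63, and some also without a vehicle library.

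Of the 15 measured cAMP/CREB target genes, 13 rose under PTH and 0 fell, and the counts were also 13 and 0 adjusted over the list alone. Beside Rgs2, Nr4a2, Nr4a3 and Pde4b, these included Junb (log2 fold change 2.39 ± 0.12). Crem, the gene of a cAMP-responsive repressor and activator, rose by 1.47 ± 0.31 (adjusted p = 0.0358). Its call ended without vehicle library 2 (1.30), vehicle library 3 (1.59), PTH library 1 (1.45) or PTH library 3 (1.22), and the list kept 9, 10 and 9 increases without PTH libraries 1, 2 and 3. In limma's camera test the list stood above the other genes with adjusted p = 4.57e-15, and adjusted p = 0.0575 with an estimated correlation. The correlation estimated for this list was -0.0354, below the preset 0.01, so the higher p-value there does not come from correlation between its genes. Phosphodiesterase genes rose together, 5 of 7 with 0 falling and 5 and 0 adjusted over the list alone: beside Pde4b and Pde8a they were Pde4d (3.03 ± 0.22), Pde5a (2.08 ± 0.16) and Pde3b (1.69 ± 0.14). The camera adjusted p was 1.28e-05, and adjusted p = 0.232 with an estimated correlation. Of 25 cAMP pathway components 2 rose and 1 fell, the same numbers as adjusted over the list alone. The salt-inducible kinase gene Sik1 rose by 2.07 ± 0.15 and the histone deacetylase gene Hdac4 by 1.47 ± 0.17, while the adenylyl cyclase gene Adcy9 had -1.07 ± 0.17, a call that ended without vehicle library 1 (-0.93), PTH library 1 (-1.03) or PTH library 3 (-1.01). The median of this list was -0.02 and its mean 0.14.

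Bone genes moved less uniformly under PTH. Of 10 PTH-responsive osteocyte and osteoblast genes 3 rose and 0 fell, also 3 and 0 adjusted over the list alone, with camera adjusted p = 0.0853, and 0.0361 at a mean level of at least 100 (adjusted p = 0.504 with an estimated correlation): Vdr, the collagenase gene Mmp13 (log2 fold change 3.67 ± 0.44) and the prostaglandin synthase gene Ptgs2 (1.20 ± 0.22), whose call ended without any 1 of vehicle libraries 2 and 3 (1.03 and 1.13) or the PTH libraries (1.17 to 1.25). Of 9 osteocyte markers 2 rose and 0 fell, as when adjusted over the list alone: Pdpn, a marker of early osteocytes, by 2.91 ± 0.40 and the gap junction gene Gja1 by 2.16 ± 0.38. The Pdpn call ended without PTH library 3 (2.77), and the Gja1 call without PTH library 1, 2 or 3 (2.17, 2.19 and 2.13). None of 15 osteoblast and bone matrix genes passed limma's test over all genes, against 2 that rose and 0 that fell adjusted over the list alone. Without vehicle library 1, 0 of them rose and 4 fell, and without vehicle library 3, 2 rose and 0 fell. Several bone genes followed that library. Pth1r had a log2 fold change of 0.02 ± 0.79 (adjusted p = 0.991) with all libraries and -1.02 (adjusted p = 8.9e-05) without vehicle library 1. Dmp1, a matrix protein gene of osteocytes, had -1.17 ± 0.58 and -1.81, Mef2c, which encodes a regulator of the sclerostin gene, -0.45 ± 0.51 and -1.11, and Sp7, the gene of the osteoblast factor osterix, -1.57 ± 0.77 and -2.58. These 3 genes passed both thresholds only without vehicle library 1. Sost (sclerostin), Tnfsf11 (RANKL) and Pde8b were not among the genes of any of the 3 tables.

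Some matrix, stress, hypoxia and inflammatory genes and 1 contractile gene also moved under PTH. Of 19 matrix remodelling genes 7 rose and 0 fell, 8 and 0 adjusted over the list alone, among them the urokinase gene Plau (log2 fold change 2.27 ± 0.14), the gelatinase gene Mmp2 (1.80 ± 0.18) and the aggrecanase genes Adamts4 (1.75 ± 0.18) and Adamts5 (1.39 ± 0.15). The camera adjusted p was 5.38e-07, and adjusted p = 0.659 with an estimated correlation. Of 17 unfolded protein and amino-acid stress genes 5 fell and 0 rose, with 8 falling adjusted over the list alone. Those that fell included Herpud1 (-1.11 ± 0.11) and Chac1 (-1.65 ± 0.22). Without PTH library 1, 2 or 3, 2 genes of this list fell. The list's camera adjusted p was 0.000574, and adjusted p = 0.687 with an estimated correlation. In fry it had adjusted p = 0.0603. In the hypoxia and glycolysis list 3 of 15 rose and 0 fell, as adjusted over the list alone: the hexokinase gene Hk2 (1.78 ± 0.11), the vascular growth factor gene Vegfa (1.46 ± 0.09) and Pfkfb3 (1.31 ± 0.13), with camera adjusted p = 0.000298 and adjusted p = 0.687 with an estimated correlation. Of 12 inflammatory and NF-kB genes 3 rose and 0 fell, also adjusted over the list alone, with the chemokine gene Cxcl1 at 2.91 ± 0.29, camera adjusted p = 0.0133 and adjusted p = 0.467 with an estimated correlation. Only 2 of them rose without vehicle library 2 or 3 or PTH library 1, 2 or 3. In the SRF/MRTF and contractile list 1 of 15 fell and 0 rose, 2 and 0 adjusted over the list alone. The gene was Lmod1 (-1.74 ± 0.26), whose call ended without PTH library 2 (-1.69) or 3 (-1.74). The camera adjusted p was 0.000574, and adjusted p = 0.285 with an estimated correlation.

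The other lists did not pass camera under PTH. Of 17 Wnt/beta-catenin targets and regulators 6 rose and 2 fell, 7 and 2 adjusted over the list alone, with the Wnt deacylase gene Notum at a log2 fold change of 2.65 ± 0.23 and the Wnt inhibitor gene Nkd2 at 1.97 ± 0.22 beside Wnt4. They numbered 3 and 0 without PTH library 1, 2 or 3. Of 16 ERK-pathway feedback genes 3 rose and 0 fell, as adjusted over the list alone, among them Fosl1 (3.55 ± 0.28) and the phosphatase gene Dusp5 (2.32 ± 0.14). The list's median was -0.06 and its mean 0.26. Of 16 BMP and TGF-beta response genes 3 rose and 0 fell, 4 and 1 adjusted over the list alone, led by the activin subunit gene Inhba at 2.02 ± 0.14, and 1 rose without PTH library 1, 2 or 3. Of 24 proliferation genes 1 fell, the cyclin gene Ccnd1 (-1.42 ± 0.13), with the same count adjusted over the list alone. Of 17 YAP/TAZ-TEAD targets 0 rose and 2 fell, as adjusted over the list alone. The fall of Ccn1 among them ended without PTH library 1, 2 or 3 (-1.45, -1.46 and -1.25). The clock gene Per1 had 1.17 ± 0.11 among 15 circadian clock genes, of which 1 rose and 1 fell, against 2 and 2 adjusted over the list alone. The fall of the clock gene Ciart ended without vehicle library 2 (-1.74) or PTH library 1, 2 or 3 (-1.61, -1.66 and -1.48). Rises and falls numbered 2 and 0 of 24 focal adhesion and integrin genes, 2 and 0 of 13 p53 and stress arrest genes, 1 and 0 of 19 cholesterol synthesis genes, the same as adjusted over the list alone in each case, and 2 and 1 of 21 interferon-stimulated genes, 3 and 1 adjusted over the list alone. Without PTH library 1, 2 or 3, 0 genes of the focal adhesion, p53 and cholesterol lists passed. The interferon list also had 0 rising and 0 falling without vehicle library 2 or 3 or PTH library 2 or 3. Markers of other cell types were few: 1 of 3 chondrocyte markers rose, Sox9 (1.33 ± 0.26, ended without vehicle library 2 (1.35) or PTH library 1, 2 or 3 (1.34, 1.31 and 1.34)), and 0 of 1 adipocyte, 2 macrophage and osteoclast, 1 endothelial and 2 muscle markers passed, against 1 endothelial marker rising and 1 muscle marker falling adjusted over the list alone.

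In all, 456 of 11775 genes passed both thresholds under PTH, 337 higher and 119 lower. The direction split depended on scaling, at 73.9% higher with the deposited scaling and 62.6% (293 higher and 175 lower) with every library scaled to the same total, which moved the median log2 fold change of all genes to -0.12. It also depended on the libraries: 614 genes passed without vehicle library 1 (375 higher and 239 lower), and 252, 245 and 219 without PTH libraries 1, 2 and 3 (41, 35 and 34 of them lower). Of the 68 named genes that passed, 41 did so in every run with 1 library left out.

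**Figure D1:**
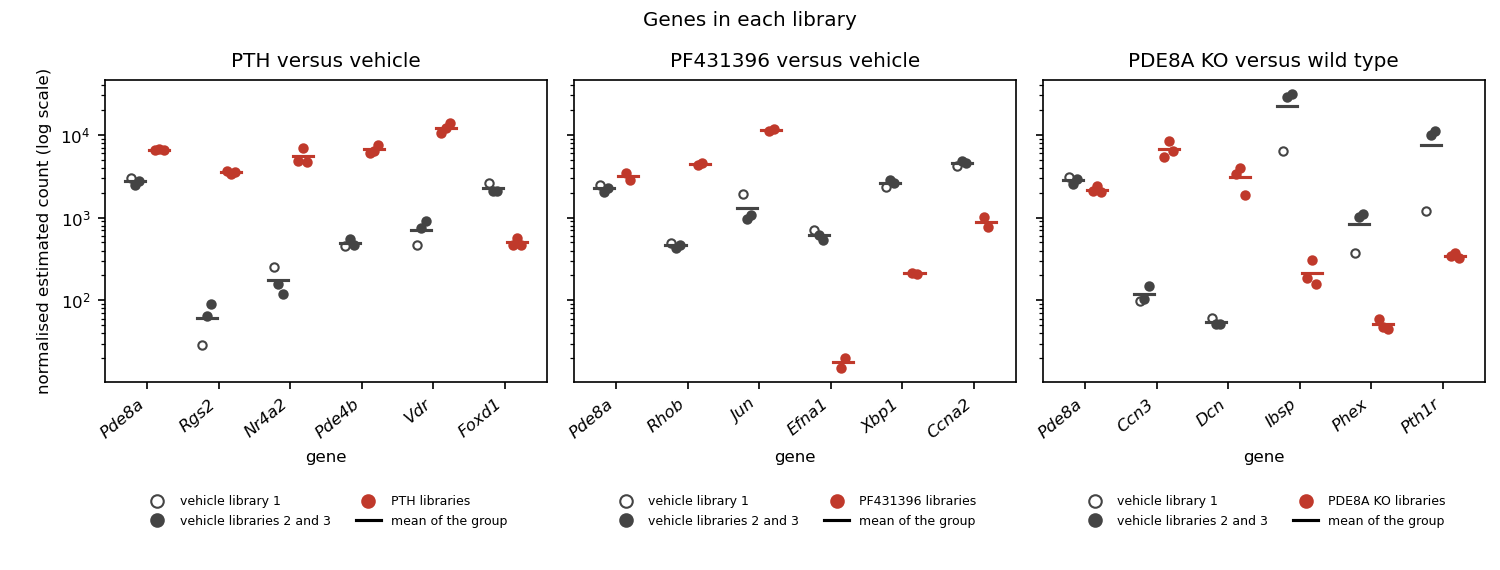
Normalised estimated counts (log axis) of 6 genes in each comparison, 1 point per library, with vehicle libraries in grey (library 1 open), treated or KO libraries in red, and a line at each group's mean. Pde8a is higher in the 3 PTH libraries, and the 3 KO libraries lie between 2037 and 2438 against 2579 to 3100 in the vehicle libraries; Ibsp and Pth1r are lower in vehicle library 1 than in the other vehicle libraries. PF431396 replicates 1 and 3, which hold the same values, are drawn as 1 point.

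PF431396 was compared with vehicle to ask what a block of FAK does to the transcripts of these cells. Efna1, which encodes the membrane-bound ligand ephrin-A1, fell from 623 ± 83.2 (n = 3) to 17.7 ± 3.67 (n = 2) normalised estimated counts, a log2 fold change of -5.06 ± 0.34 (adjusted p = 0.00247). Rhob, which encodes a small GTPase of the actin cytoskeleton, rose from 463 ± 35.7 to 4480 ± 170 (3.27 ± 0.18, adjusted p = 0.00247), and the early-response transcription factor gene Jun from 1316 ± 523 to 11348 ± 443 (3.18 ± 0.31, adjusted p = 0.00262). Xbp1, a transcription factor gene of the unfolded protein response, fell from 2594 ± 232 to 211 ± 4.51 (-3.61 ± 0.19, adjusted p = 0.00247). The genes of the drug's targets did not pass, with Ptk2 at 0.08 ± 0.20 (adjusted p = 0.788) and Ptk2b at 1.48 ± 0.64 (adjusted p = 0.113), and Pde8a had 0.48 ± 0.17 (adjusted p = 0.0685). With every library scaled to the same total they had -0.46, 0.97 and -0.05, while the median of all genes moved from -0.02 to -0.55. In GRCm38 Efna1 lies on the minus strand of chromosome 3 from 89271733 to 89281142 and Rhob on the minus strand of chromosome 12 from 8497661 to 8500009.

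Further large increases were the complement gene C3 (log2 fold change 3.28 ± 0.22), Ltbp2, which encodes a matrix protein related to TGF-beta binding proteins (3.24 ± 0.31), Thsd7a (3.27 ± 0.44) and the processed pseudogene Morf4l1-ps1 (3.40 ± 0.43). Ncf4 (3.49 ± 0.76), Ccdc62 (3.25 ± 0.82), the carbonic anhydrase gene Car9 (3.21 ± 0.70) and Mmp13 (3.07 ± 0.53) rose as well. Their calls ended in runs that left 1 PF431396 library: Ncf4 did not pass without PF431396 library 2 (2.71), Ccdc62 without library 1 (2.05), and Car9 and Mmp13 without either (3.29 and 3.13 for Car9, 3.13 and 3.00 for Mmp13). The large decreases passed in every run with 1 library left out: Tent5c (-4.20 ± 0.41), Tmem177 (-4.17 ± 0.34), Nsmce3 (-4.17 ± 0.33), the glutathione-degrading enzyme gene Chac1 (-4.12 ± 0.31), the importin gene Kpna2 (-4.05 ± 0.30), the sphingosine 1-phosphate receptor gene S1pr2 (-4.04 ± 0.36), Hgh1 (-4.03 ± 0.37), Spin4 (-4.01 ± 0.37) and the zinc finger gene Zfp260 (-3.98 ± 0.38).

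Some stress, cell cycle, sterol and clock genes fell under PF431396. Of 17 unfolded protein and amino-acid stress genes 9 fell and 0 rose, 10 and 0 adjusted over the list alone, among them Chac1, Xbp1, Dnajb9 (log2 fold change -2.24 ± 0.19) and Herpud1 (-2.14 ± 0.16), with camera adjusted p = 0.000574 and adjusted p = 0.687 with an estimated correlation. Of 24 proliferation genes 8 fell and 0 rose, also adjusted over the list alone, with the mitotic kinase genes Aurka at -3.17 ± 0.31 and Plk1 at -2.93 ± 0.29, the cyclin gene Ccna2 at -2.37 ± 0.18 and Cdk1 at -1.44 ± 0.15. Their camera adjusted p was 0.00238, and adjusted p = 0.467 with an estimated correlation. Of 19 cholesterol synthesis genes 8 fell and 0 rose, also adjusted over the list alone, including Hmgcs1 (-2.63 ± 0.38), Mvd (-2.55 ± 0.35) and Msmo1 (-1.90 ± 0.26). The number that fell was 16 without vehicle library 1 and 3 without PF431396 library 1 or 2, the camera adjusted p was 0.00177, and adjusted p = 0.725 with an estimated correlation. Of 15 circadian clock genes 6 fell and 0 rose, also adjusted over the list alone, with the clock repressor genes Bhlhe40 (-2.57 ± 0.38), Nr1d1 (-2.34 ± 0.34) and Bhlhe41 (-1.83 ± 0.21). The camera adjusted p was 0.0431, and adjusted p = 0.566 with an estimated correlation, and 3 genes fell without PF431396 library 1 or 2. At a mean level of at least 100 the camera adjusted p of the clock list was 0.0729. With every library scaled to the same total, the falls numbered 10, 14, 13 and 9 in these 4 lists.

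Some matrix, adhesion and contractile genes rose under PF431396 with the deposited scaling. Over all genes tested 26.2% passed both thresholds, so a list with about that share passing does not stand out by its count. Fold changes depended on level with that scaling. Random lists matched on level to the ribosomal protein and collagen genes had medians of 0.64 and 0.36, and all genes -0.02. Camera does not match on level, so these lists were not set against genes of like level. Of 19 matrix remodelling genes 12 rose and 0 fell, 13 and 1 adjusted over the list alone, among them Mmp2 (log2 fold change 1.92 ± 0.19), Plau (1.40 ± 0.24), the metalloproteinase inhibitor gene Timp2 (1.38 ± 0.20) and the fibronectin gene Fn1 (1.17 ± 0.13). Their camera adjusted p was 0.000184, and adjusted p = 0.687 with an estimated correlation, and 6 and 4 rose without PF431396 libraries 1 and 2. Of 24 focal adhesion and integrin genes 4 rose and 1 fell, 5 and 1 adjusted over the list alone: the integrin genes Itgav (1.44 ± 0.15) and Itgb1 (1.28 ± 0.13) rose, and Bcar1, which encodes a FAK-binding scaffold, had -1.77 ± 0.17. The camera adjusted p was 0.0338, and adjusted p = 0.566 with an estimated correlation, and 0.0503 at a mean level of at least 100. Without PF431396 library 2, 2 rose and 2 fell. Of 15 SRF/MRTF and contractile genes 4 rose and 0 fell, also adjusted over the list alone, such as the myosin light chain gene Myl9 (1.24 ± 0.19) and the tropomyosin gene Tpm2 (2.07 ± 0.42, ended without PF431396 library 1 (2.12) or 2 (2.02)), with camera adjusted p = 0.0177 and adjusted p = 0.566 with an estimated correlation. Without PF431396 library 1 or 2, 2 of this list rose. Scaling every library to the same total lowered the median log2 fold change of all genes to -0.55, and these lists then had 4 rising and 2 falling, 1 and 2, and 1 and 1 members past the thresholds. Mmp2 and Bcar1 passed there, while Itgb1 (0.74), Itgav (0.91), Fn1 (0.63), Timp2 (0.85), Plau (0.87) and Myl9 (0.71) did not.

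Bone, cAMP and immune genes were mixed under PF431396. Of 15 osteoblast and bone matrix genes 4 rose and 1 fell, also adjusted over the list alone. The osteopontin gene Spp1 rose by a log2 fold change of 2.29 ± 0.33, the periostin gene Postn by 2.29 ± 0.36 and the osteocalcin genes Bglap and Bglap2 by 1.72 ± 0.37 and 1.51 ± 0.28. Without PF431396 library 1 or 2, Spp1 alone of these 4 passed, with Postn at 2.33 and 2.25, Bglap at 1.74 and 1.70, and Bglap2 at 1.51 in both. Bglap2 also did not pass with equal totals (0.98). With equal totals this list had 3 rising and 2 falling. Without vehicle library 1, 6 of the list rose and 3 fell, and Pth1r had -1.16 (adjusted p = 0.00238) against -0.11 ± 0.94 (adjusted p = 0.939) with all libraries. Of 10 osteocyte markers 1 rose and 1 fell, also adjusted over the list alone: Fbln7 (1.26 ± 0.25) and the homeobox gene Irx5 (-2.87 ± 0.60), neither of which passed without PF431396 library 1 (1.17 and -2.92) or 2 (1.35 and -2.82), nor Fbln7 with equal totals (0.73). Of 10 PTH-responsive genes 1 rose and 1 fell, also adjusted over the list alone: Mmp13 and the cytokine gene Lif (-2.96 ± 0.60), which did not pass without PF431396 library 1 (-3.03) or 2 (-2.88). Dmp1 had -0.05 ± 0.79, Mef2c 0.23 ± 0.60 and Nr4a2 0.64 ± 0.41, none past the test. Of 13 cAMP/CREB target genes 3 rose and 2 fell, also adjusted over the list alone, with Junb at 1.54 ± 0.17 and Avpi1 at -2.12 ± 0.40. The list's median was -0.27 and its mean 0.06, and 1 rose and 1 fell without PF431396 library 2. With equal totals 2 rose and 5 fell.

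Among immune lists, 4 of 12 inflammatory and NF-kB genes rose and 1 fell under PF431396, also adjusted over the list alone: C3, Il1rl1 (log2 fold change 3.02 ± 0.44) and the adhesion molecule gene Vcam1 (2.03 ± 0.36) rose, and the NF-kB inhibitor gene Nfkbia had -3.35 ± 0.27. This list's median was 0.37, and -0.15 with equal totals. Of 18 interferon-stimulated genes 3 rose and 6 fell, also adjusted over the list alone, such as Isg15 (-2.06 ± 0.39), and 1 rose and 1 fell without PF431396 library 2. Of 12 p53 and stress arrest genes 1 rose and 5 fell, 1 and 6 adjusted over the list alone: the cell cycle inhibitor gene Cdkn1a had -2.11 ± 0.21, and 2 and 1 of the list fell without PF431396 libraries 1 and 2 and 3 without vehicle library 2 or 3. Of 16 YAP/TAZ-TEAD targets 2 rose and 3 fell, also adjusted over the list alone, with Amotl2 at -1.78 ± 0.24 and Ajuba at -1.38 ± 0.21. The rise of the receptor kinase gene Axl ended without vehicle library 1 (0.97) or PF431396 library 1 (0.80). Of 16 BMP and TGF-beta response genes 1 rose and 2 fell, 0 and 2 adjusted over the list alone, the ligand genes Bmp4 (-1.85 ± 0.24) and Bmp2 (-1.63 ± 0.26) falling. The rise was that of Tgfbi, which ended without vehicle library 3 (2.10) or PF431396 library 1 (2.04) or 2 (1.75). Of 14 hypoxia and glycolysis genes 4 rose and 2 fell, 7 and 2 adjusted over the list alone, with Hk2 at -2.17 ± 0.19 and Pfkfb3 at -1.29 ± 0.21. None rose without PF431396 library 1 or 2. Rises and falls numbered 5 and 1 of 17 Wnt genes (5 and 2 adjusted over the list alone), 4 and 1 of 25 cAMP pathway components (the same), 1 and 0 of 8 phosphodiesterases and 1 and 0 of 16 ERK-pathway feedback genes (0 and 0 for each adjusted over the list alone). Without PF431396 libraries 1 and 2 the Wnt list had 0 rising and 3 falling, and 1 and 0, and the cAMP pathway list 2 and 1, and 0 and 0. With equal totals the rises and falls numbered 3 and 2 in the inflammatory list, 0 and 8 in the interferon, 0 and 9 in the p53, 0 and 5 in the YAP/TAZ-TEAD, 0 and 3 in the BMP and TGF-beta and 1 and 3 in the hypoxia list. They numbered 1 and 6 of the Wnt genes, 1 and 4 of the cAMP pathway components, 0 and 1 of the phosphodiesterases and 0 and 8 of the ERK-pathway feedback genes. There the medians of the cAMP pathway list (-0.37), the phosphodiesterases (-0.25) and the PTH-responsive genes (-0.35) turned from positive to negative, with the median of all genes (-0.55), and stayed above it. The macrophage and osteoclast markers Cd68, a lysosomal protein gene, and Ctsk, the cathepsin K gene, both rose, by 2.57 ± 0.36 and 2.32 ± 0.23. Of 4 chondrocyte markers 2 rose, Comp (2.36 ± 0.47, ended without PF431396 library 1 at 1.99) and Sox6 (2.03 ± 0.47, ended without PF431396 library 1 or 2 at 2.38 and 1.68), the adipocyte marker Cebpa had -2.31 ± 0.45, and the 1 endothelial and 2 muscle markers did not pass.

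In all, 3005 of 11484 genes passed both thresholds under PF431396, 1257 higher and 1748 lower, and the count was 1756 without PF431396 library 2 (n = 1 against 3), 570 higher and 1186 lower. The direction split depended on scaling more than in the other comparisons: 41.8% were higher with the deposited scaling and 9.02% with every library scaled to the same total (344 higher and 3470 lower), so each direction holds relative to the other genes. Of the 90 named genes that passed, 55 did so in every run with 1 library left out.

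The comparison of the KO with wild-type cells asks what the loss of Pde8a does to transcripts. Pde8a transcripts were still counted in the KO. They stood at 2074, 2438 and 2037 normalised estimated counts in the 3 KO libraries, against 3100, 2579 and 2890 in the vehicle libraries, a log2 fold change of -0.39 ± 0.14 (adjusted p = 0.0681). Each KO library lay below each vehicle library, and the exact permutation test of the means gave a two-sided p = 0.1, the smallest that 3 against 3 allows. The tables give 1 value per gene and no exon-level values, so they do not show the deletion itself. The number of KO clones is not given in the sources used here. Other differences between the KO and wild-type cells therefore cannot be told apart from effects of the loss of Pde8a.

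The largest changes in the KO included matrix genes that rose and bone genes that fell. Ccn3, which encodes a matricellular protein, rose from 118 ± 28.1 to 6706 ± 1490 normalised estimated counts (n = 3 in each group; log2 fold change 5.81 ± 0.23, adjusted p = 3.73e-05), and the decorin gene Dcn from 55.2 ± 5.14 to 3076 ± 1092 (5.71 ± 0.29, adjusted p = 7.49e-05). Panx3, a pannexin channel gene of bone and cartilage cells, fell from 5980 ± 4675 to 27.2 ± 15.0 (-7.19 ± 0.98, adjusted p = 0.00228), and Ibsp from 22178 ± 13786 to 216 ± 79.9 (-6.42 ± 0.59, adjusted p = 0.000513). Pth1r had -3.90 ± 0.76 (adjusted p = 0.0096), with 344, 370 and 322 normalised estimated counts in the KO libraries against 1204, 10083 and 11261 in vehicle libraries 1, 2 and 3, and -4.95 without vehicle library 1. In GRCm38 Ccn3 lies on the plus strand of chromosome 15 from 54745702 to 54754039, Dcn on the plus strand of chromosome 10 from 97479609 to 97518143, Ibsp on the plus strand of chromosome 5 from 104299171 to 104311469 and Panx3 on the minus strand of chromosome 9 from 37659902 to 37669235.

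Further large increases in the KO were Edil3, which encodes an integrin-binding matrix protein (log2 fold change 5.48 ± 0.22), Tspan7 (5.25 ± 0.33), the laminin gene Lama2 (4.93 ± 0.47), Medag (4.69 ± 0.25), Vcam1 (4.42 ± 0.21), Cxadr (4.37 ± 0.29), Hmcn1 (4.37 ± 0.81) and Il1rl1 (4.37 ± 0.30). The large decreases were Smpd3, the gene of a sphingomyelinase needed for bone mineralisation (-6.64 ± 0.83), the growth factor gene Tgfa (-6.26 ± 0.41), the skeletal actin gene Acta1 (-5.85 ± 0.62), the sphingosine 1-phosphate exporter gene Spns2 (-5.75 ± 0.57), Sorcs2 (-5.64 ± 0.38), the collagen gene Col11a2 (-5.37 ± 0.36), the guidance ligand gene Slit3 (-5.36 ± 0.25) and the actin nucleator gene Cobl (-5.31 ± 0.31). All 20 genes with the largest changes passed in every run with 1 library left out.

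Of 15 osteoblast and bone matrix genes 9 fell and 0 rose in the KO, also adjusted over the list alone. Beside Ibsp and Pth1r, the alkaline phosphatase gene Alpl had a log2 fold change of -2.95 ± 0.52 and Postn -1.84 ± 0.34. The list's camera adjusted p was 0.000574, and adjusted p = 0.691 with an estimated correlation. In limma's fry test, which asks whether a list's genes move on balance 1 way, it had adjusted p = 0.0824, and 0.00490 without vehicle library 1. Vehicle library 1, low in the same genes, lay between the other vehicle libraries and the KO for Ibsp, Panx3, Pth1r and Alpl (4670 against 17710 and 21088 in vehicle libraries 2 and 3, and 1587 ± 360 in the KO), and without it 12 of the list fell; without KO library 1, 6 fell. Of 9 osteocyte markers 2 rose and 3 fell, also adjusted over the list alone: Phex, an endopeptidase gene of phosphate control, had -3.86 ± 0.41 and Dmp1 -2.84 ± 0.59, while Pdpn rose by 2.45 ± 0.40 and Fbln7 by 2.18 ± 0.21. The Dmp1 call ended without KO library 2 (-2.85, limma adjusted p = 0.0503) or 3 (-2.50, limma adjusted p = 0.0507). The median of this list was 0.64 and its mean -0.13. Of 10 PTH-responsive genes 1 rose and 4 fell, also adjusted over the list alone, with Lif at -2.89 ± 0.50, and 6 fell without vehicle library 1 and 2 without KO library 1, 2 or 3. Mef2c had -1.34 ± 0.53 (adjusted p = 0.0957) with all libraries and -2.01 past both thresholds without vehicle library 1.

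The cAMP/CREB target genes as a list did not pass camera in the KO: 1 of 15 rose and 0 fell, also adjusted over the list alone, the GTPase gene Gem at a log2 fold change of 1.91 ± 0.26, with adjusted p = 0.284 in camera and 0.0427 in fry. Nr4a2 had 0.45 ± 0.30 (adjusted p = 0.294) and Crem -0.12 ± 0.25 (adjusted p = 0.753). Of 8 phosphodiesterases 2 rose and 0 fell, also adjusted over the list alone, Pde5a by 1.45 ± 0.13 and Pde3b by 1.08 ± 0.15. Of 24 cAMP pathway components 3 rose and 0 fell, also adjusted over the list alone: the adenylyl cyclase gene Adcy7 (2.41 ± 0.14), Prkar2b, which encodes a regulatory subunit of protein kinase A (1.36 ± 0.18), and the anchoring protein gene Akap12 (1.35 ± 0.22).

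Interferon-stimulated genes rose in the KO, 12 of 21 with 0 falling, also adjusted over the list alone, among them Ifit3 (log2 fold change 2.26 ± 0.25), the chemokine gene Cxcl10 (2.16 ± 0.26), Isg15 (1.96 ± 0.18) and Ifit1 (1.61 ± 0.19). Their camera adjusted p was 4.59e-06, and adjusted p = 0.687 with an estimated correlation. The number was 8 without KO library 3 and 14 without vehicle library 1. Of 18 matrix remodelling genes 7 rose and 1 fell, also adjusted over the list alone: the fibrillin gene Fbn1 (2.43 ± 0.24), Mmp2 (1.89 ± 0.18) and Loxl1 (1.59 ± 0.14) rose and the tenascin gene Tnc had -2.65 ± 0.26, with camera adjusted p = 0.00132 and adjusted p = 0.687 with an estimated correlation. Of 24 focal adhesion and integrin genes 4 rose and 0 fell, also adjusted over the list alone, including the integrin gene Itga6 (3.87 ± 0.25), the caveolin gene Cav1 (2.82 ± 0.28) and Bcar1 (1.04 ± 0.11), with camera adjusted p = 0.0338 and adjusted p = 0.566 with an estimated correlation, and Ptk2 had 0.29 ± 0.11 and Ptk2b -0.21 ± 0.48, neither past the test. Without vehicle library 1 the focal adhesion list had a camera adjusted p of 0.0605. Of 17 ERK-pathway feedback genes 5 rose and 0 fell, also adjusted over the list alone, such as Fosl1 (2.54 ± 0.31), Egr3 (1.45 ± 0.26) and Dusp5 (1.41 ± 0.17), and 8 rose without vehicle library 1. Their camera adjusted p was 0.00434, and adjusted p = 0.687 with an estimated correlation.

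The remaining lists did not pass camera in the KO with all libraries. Without vehicle library 1, the cholesterol synthesis (camera adjusted p = 5.24e-05), PTH-responsive (0.0214) and BMP and TGF-beta response (0.0440) lists stood below the other genes, against adjusted p = 0.178, 0.103 and 0.436 with all libraries. With an estimated correlation they had adjusted p = 0.703, 0.573 and 0.662 without that library. Of 12 inflammatory and NF-kB genes 5 rose and 2 fell, also adjusted over the list alone, with Vcam1 and Il1rl1 rising and C3 (log2 fold change -2.20 ± 0.27) and the lipocalin gene Lcn2 (-2.51 ± 0.44) falling, and 3 rose without KO library 1 or 2. Of 17 YAP/TAZ-TEAD targets 2 rose and 2 fell, also adjusted over the list alone, with Ccn2 at -2.55 ± 0.15 and the receptor kinase gene Axl at 1.22 ± 0.12. Of 15 SRF/MRTF and contractile genes 1 rose and 1 fell, also adjusted over the list alone: Tpm2 (2.14 ± 0.34) and the smooth muscle actin gene Acta2 (-1.68 ± 0.18). Of 15 Wnt genes 2 rose and 3 fell, 3 and 4 adjusted over the list alone, with the transcription factor gene Tcf7 at -2.18 ± 0.34 and the Wnt antagonist gene Sfrp2 at 2.29 ± 0.43, and 6 fell without vehicle library 1. Of 14 BMP and TGF-beta response genes 0 rose and 3 fell, also adjusted over the list alone, such as Skil (-1.39 ± 0.21), and 5 fell without vehicle library 1. Of 12 p53 and stress arrest genes 3 rose and 1 fell, also adjusted over the list alone, with Eda2r at 1.88 ± 0.35 and Cdkn1a at -1.26 ± 0.23. None of 24 proliferation and 17 unfolded protein genes passed, over all genes or adjusted over the list alone, with unadjusted p below 0.05 in 4884 of the 11592 genes tested by limma. Rises and falls numbered 0 and 1 of 19 cholesterol synthesis genes, 1 and 0 of 14 hypoxia and glycolysis genes and 1 and 1 of 14 circadian clock genes, the same as adjusted over the list alone. Without vehicle library 1, 3 of the cholesterol synthesis genes fell. In the hypoxia list 3 and 4 rose without vehicle libraries 2 and 3 and 0 without KO library 1 or 2, and the clock list had 0 rising and 0 falling without vehicle library 1 or KO library 1 or 2. Of the other cell types, Ctsk (1.52 ± 0.26) among 2 macrophage and osteoclast markers and Sox9 (1.33 ± 0.32) among 3 chondrocyte markers rose, the latter not past the test without KO library 1 (1.14) or 2 (1.29). Of 2 muscle markers Acta1 fell and Des rose by 1.24 ± 0.35, a call that ended without vehicle library 3 (0.98) or KO library 1, 2 or 3 (1.30, 1.22 and 1.18). The 1 adipocyte marker did not pass, and 0 endothelial markers were listed.

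In all, 1328 of 11592 genes passed both thresholds in the KO, 733 higher and 595 lower. With 1 library left out the count ranged from 967 to 1405, the latter without vehicle library 1 and with 699 higher and 706 lower. Of the 76 named genes that passed, 63 did so in every run with 1 library left out.

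**Figure D2:**
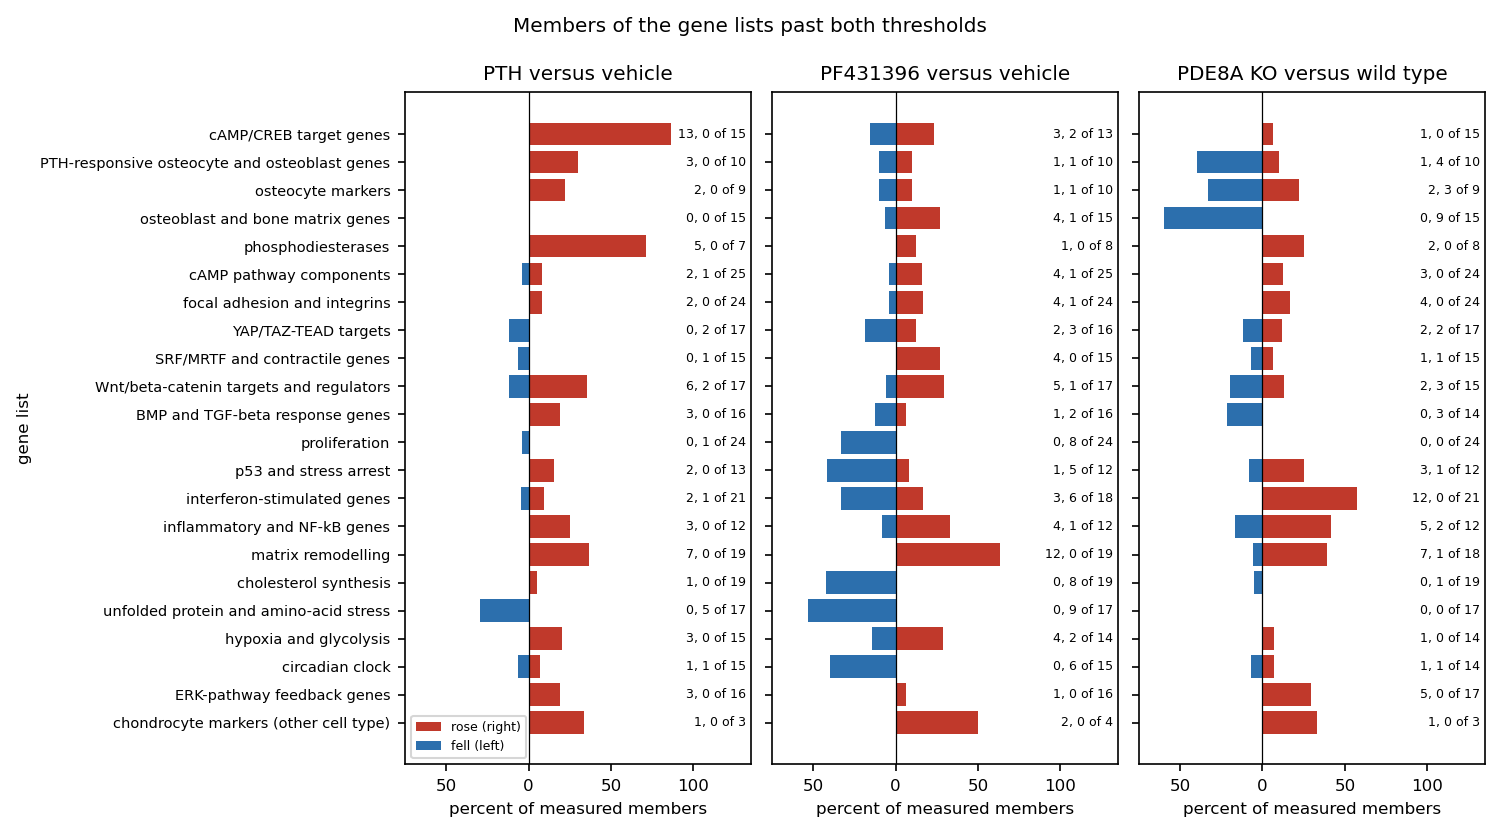
Percent of the measured members of each gene list that passed both thresholds in limma, rising (red, to the right) or falling (blue, to the left). The numbers that rose and fell and the number measured stand beside each bar. Over all genes tested, 3.87% passed under PTH, 26.2% under PF431396 and 11.5% in the KO. The cAMP/CREB target genes rose in 13 of 15 under PTH against 1 of 15 in the KO, and the osteoblast and bone matrix genes fell in 9 of 15 in the KO; with every library scaled to the same total, PF431396 rises become fewer and falls more numerous.

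The 3 comparisons share their vehicle libraries, so their correlations were set against groups simulated without change. PTH and the KO shared 110 genes past the thresholds in the same direction, 81 higher and 29 lower, where independent lists would share 20.4 and 5.87, and 19 genes in opposite directions. Numbers for independent lists take no account of the shared libraries. The count was 52, 53 and 49 without PTH libraries 1, 2 and 3, and 161 without vehicle library 1. Those 161 were 80 higher and 81 lower. PTH and PF431396 shared 83 genes (46 higher and 37 lower, against 34.7 and 17.9 for independent lists) and had 47 in opposite directions, and the shared number was 51 without vehicle library 2, 42, 39 and 39 without PTH libraries 1, 2 and 3, and 44 and 43 without PF431396 libraries 1 and 2. Other sets of genes passed under other settings, 50 higher and 69 lower without vehicle library 1, and 16 higher and 80 lower with every library scaled to the same total, which lowers all PF431396 fold changes. PF431396 and the KO shared 296 genes, 221 higher and 75 lower, against 72.4 and 89.7 for independent lists, with 95 in opposite directions. The number was 165 and 130 without PF431396 libraries 1 and 2, and with every library scaled to the same total it was 257, now 91 higher and 166 lower. In opposite directions (first higher, then first lower), PTH and the KO had 15 and 4 genes against 17.1 and 6.98 for independent lists. PTH and PF431396 had 42 and 5 against 49.3 and 12.6, and PF431396 and the KO 60 and 35 against 62.7 and 104. Across genes, which are not independent replicates, log2 fold changes had r = 0.195 for PTH with the KO. They had r = 0.0816 for PTH with PF431396 and 0.165 for PF431396 with the KO. The shared vehicle libraries alone gave r = 0.762, 0.524 and 0.519 in the simulations. The simulated groups held no change, and change that 1 group does not share lowers r. A lower observed r therefore does not show that the responses are unlike. The covariance exceeded the simulated one by 0.0295 and 0.0796 in the pairs of the KO with PTH and with PF431396, and the difference was -0.0114 for PTH with PF431396. Without vehicle library 1 these 3 differences were 0.0604, 0.0850 and -0.0269, with r = 0.178, 0.123 and -0.0231.

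Across all 3 comparisons 26 genes passed in the same direction, 16 higher and 10 lower. The count was 42 (15 higher and 27 lower) without vehicle library 1, 17 without vehicle library 2, 12, 12 and 13 without PTH libraries 1, 2 and 3, 13 and 11 without PF431396 libraries 1 and 2, and 24 (8 higher and 16 lower) with every library scaled to the same total. The 6 ranked first by their smallest change in any comparison were all higher. The co-stimulatory receptor gene Tnfrsf9 had log2 fold changes of 3.60 under PTH, 2.89 under PF431396 and 2.33 in the KO. Stac2 had 2.96, 1.97 and 3.44, Adamtsl4 2.53, 2.31 and 2.24, the heparin-binding growth factor gene Ptn 2.08, 2.08 and 2.09, Mmp2 1.80, 1.92 and 1.89, and the thrombospondin gene Thbs2 1.58, 1.57 and 2.38. Of these, Mmp2 and Thbs2 passed in every run with 1 library left out. The PTH calls of Adamtsl4 and Ptn ended without PTH library 1, 2 or 3 (2.58, 2.58 and 2.42 for Adamtsl4, 2.18, 2.17 and 1.88 for Ptn). The PF431396 calls of Tnfrsf9, Adamtsl4 and Ptn ended without PF431396 library 1 (2.72, 2.23 and 2.25) or 2 (3.06, 2.38 and 1.92), and that of Stac2 without library 2 (1.89).

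Other genes passed in opposite directions with the deposited scaling. Slit3 rose under PF431396 (1.09) and had -5.36 in the KO, a difference of 6.44 ± 0.26 (adjusted p = 4.97e-06 in the direct contrast). The amino acid transporter gene Slc36a2 had 1.64 under PF431396 and -4.72 in the KO, the laminin gene Lama5 1.27 and -4.29, and C3 3.28 and -2.20. With every library scaled to the same total Slit3 (0.55), Slc36a2 (1.11) and Lama5 (0.74) did not pass under PF431396. Nor did they without PF431396 library 1 (1.10, 1.65 and 1.08) or 2 (1.08, 1.64 and 1.46), or Slit3 without vehicle library 1 (0.91). Scube3 rose under PTH (1.44) and had -4.70 in the KO, a difference of 6.14 ± 0.26. Its PTH call ended without PTH library 1, 2 or 3 (log2 fold changes of at least 1.36). The mesenchymal transcription factor gene Snai1 rose under PTH (3.52) and had -2.04 under PF431396, a difference of 5.57 ± 0.23. Rgs2 was 6.92 ± 0.36 log2 units higher under PTH than in the KO (adjusted p = 1.46e-06) and 6.24 ± 0.58 higher than under PF431396. Pde8a itself was 1.65 ± 0.11 log2 units higher under PTH than in the KO (adjusted p = 5.31e-06). Tested directly over the 11095 genes of all 3 tables, 1706 differed past both thresholds between PTH and the KO, 3745 between PTH and PF431396 and 3579 between PF431396 and the KO.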

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

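Scaling every library to the same total, the authors' deposited calls, the 3 PF431396 columns taken as 3 libraries, and the overlaps and the genes shared by all 3 comparisons without each library were chosen after the data were seen. With adjusted p alone the counts were 908 for PTH and 3223 for the KO, and the overlaps 187 for PTH with PF431396, 260 for PTH with the KO and 918 for PF431396 with the KO, because that setting drops a criterion. At adjusted p below 0.01 the counts were 261 for PTH and 1531 for PF431396, as a stricter threshold gives. With an estimated correlation 0 of the 66 list tests in limma's camera passed, against 19 with the preset one, 18 with members at a mean level of at least 100 and 21 without vehicle library 1. For the cAMP/CREB targets under PTH the estimated correlation was -0.0354, below the preset 0.01. Their unadjusted camera p still went from 6.92e-17 to 0.000871. That setting also rests on the few libraries of each fit. It therefore does not show that correlation between genes accounts for all 19 passes. Among the other lists passing under PTH, the estimated correlation was -0.142 for phosphodiesterases, -0.0408 for inflammatory and -0.00936 for SRF/MRTF genes. It was 0.523 for matrix remodelling, 0.451 for unfolded protein and 0.899 for hypoxia genes. For the latter lists, correlation between genes is not excluded as a reason for the pass. In fry, adjusted over the same tests, 4 lists that passed camera did not pass: unfolded protein (adjusted p = 0.0603) and hypoxia (0.0544) under PTH, cholesterol synthesis under PF431396 (0.132) and osteoblast genes in the KO (0.0824). All 4 passed fry without vehicle library 1 (0.00880, 0.00288, 0.00394 and 0.00490). The authors' deposited calls gave an overlap of 150 for PTH with PF431396. Their lists were longer, with 672 genes for PTH and 3533 for PF431396. Their PF431396 fold changes match means over all 3 columns, of which those of replicates 1 and 3 were identical. How far either accounts for the overlap was not tested. Leaving out 1 library gave 219 to 614 genes for PTH, 1756 to 2917 for PF431396 and 967 to 1405 for the KO, and overlaps of 39 to 119 for PTH with PF431396, 49 to 161 for PTH with the KO and 130 to 310 for PF431396 with the KO. A PF431396 group left with 1 library is assumed to vary like the vehicle libraries. Pth1r under PTH ranged from -1.02 without vehicle library 1 to 0.58 without vehicle library 3, against 0.02 with all libraries, and the cause was not tested. With the replicate number as a block the counts were 403 for PTH and 1305 for the KO. Other counts stayed within 1.5 times: 437, 2851 and 1177 genes at a mean level of at least 100, 455, 2964 and 1317 with upper-quartile scaling, 468, 3814 and 1329 with equal totals, 526, 3467 and 1298 with all groups in 1 fit, and 3425 for PF431396 with 3 columns. A like count can hold other genes: with equal totals, 2092 of the 3005 PF431396 calls (69.6%) were kept in the same direction. Of 4598 values of named genes under the alternatives, 4303 kept their side of the thresholds and 229 no longer passed. Another 65 passed only there, and 1 passed only there with another sign than with all libraries. In all 36 values changed sign, 0 of them of genes that passed with all libraries and the deposited scaling. No filter on low values and a minimum mean level of 10 remove no gene. A test on recovered counts, the authors' tool with its own size factors, a block for PF431396, whose identical columns leave the replicate numbers unclear, and a split of the vehicle libraries were not run. Genes below 11 estimated counts in any library of a table are outside these results.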

Other observations

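Gene families outside the fixed lists also moved. The mitochondrial and zinc finger genes were taken up for the pattern that they showed in these data. The other families were chosen after their values were seen. Under PF431396, with the deposited scaling, 72 of 92 ribosomal protein genes rose and 2 fell in limma (median log2 fold change 1.38), where 10000 random lists matched on level had medians from 0.41 to 0.87, and 16 rose and 3 fell with equal totals (0.84). Collagen genes rose in 15 of 24 with 0 falling (median 1.60), and in 8 with equal totals (median 1.07), and 14 of 37 complex I subunit genes encoded in the nucleus rose with 0 falling (median 0.84), where equal totals left 2 rising and 1 falling (median 0.30). The X chromosome's 347 genes had a median of 0.33, and -0.20 with equal totals, which moved the median of all genes from -0.02 to -0.55, so that these genes stayed above the others.

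Under PTH the 24 collagen genes had a median of 0.43, above the matched random lists (-0.10 to 0.22), with 2 rising, and 0.31 with equal totals. The 334 Zfp genes had a median of 0.15, and 0.03 with equal totals. In the KO, 91 ribosomal protein genes had a median of -0.28, against -0.11 to 0.14 in random lists, with 0 rising and 3 falling, and 37 complex I genes a median of 0.37, against -0.22 to 0.19, with 1 rising. Collagen genes had 8 rising and 3 falling of 21.

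The tests on mitochondrial scaling, on the cAMP/CREB target and ERK-pathway feedback lists and on chromosome segments were chosen only after the result was seen. The other chromosome tests were added after the medians of whole chromosomes had been seen. Vehicle library 1 lay at least 1 log2 unit above vehicle libraries 2 and 3 in 486 genes of the PTH table and as far below in 1094, where libraries 2 and 3 were as far apart in 134. A wrong label would put it at the level of another group. On a scale from 0 (vehicle libraries 2 and 3) to 1 (the other group), its median position was 0.149 for the KO, -0.00884 for PTH and -0.0929 for PF431396, all far from 1. Transcript length and GC content explained little, since removing their trend left 0.957 of the variance. The design names no biological difference between vehicle libraries, so no biological explanation was tested.

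Under PF431396 mitochondrial transcripts were higher and zinc finger (Zfp) transcripts lower. The 13 mitochondrial genes had a median log2 fold change of 1.91. In limma 11 of them passed both thresholds with the deposited scaling and 11 with every library scaled to the same total. The choice between these scalings therefore does not account for the rise. Equal totals compare shares of counts, which had already been seen to be higher. Both scalings are relative, so a rise of mitochondrial transcripts cannot be told apart from a fall of the others. The 1027 nuclear genes in the same range of GC content had a median of -0.14. The 288 Zfp genes had 5 rising and 100 falling (median -0.69), below 100% of the matched random lists, and 1 rising and 154 falling with equal totals (median -1.22). After removal of a trend on length and GC their median residual was -0.56, outside the -0.19 to 0.12 of random lists. The low Zfp median is the pattern itself and no table measures how long transcripts last, so a fall of short-lived transcripts cannot be told apart from other causes. The 29 listed members of the cAMP/CREB target and ERK-pathway feedback lists, which include immediate-early genes, had 4 rising and 2 falling. Their median of -0.48 lay within the -0.60 to 0.44 of random lists and does not decide on a general fall of short-lived transcripts.

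In the KO the median log2 fold changes of whole chromosomes differed, from -0.38 on chromosome 18 to 0.28 on chromosome 15. The SD of the 19 autosome medians was 0.186, against at most 0.0544 in 1000 shuffles of genes between autosomes. It was not set by vehicle library 1, since 0.982 of the SD was left against vehicle libraries 2 and 3, nor by length, GC content and level, since 0.921 was left. A change of chromosome copy number in the KO cells might give such medians and would move both parts of a chromosome together. The 19 autosomes were each divided at their middle listed gene. The medians of both parts had r = 0.377 (permutation p = 0.113) and rho = 0.288 (permutation p = 0.233). Without the 2 autosomes whose first part lay farthest from the median it was r = 0.591, and without the 2 farthest as a whole r = 0.101. The latter were chromosomes 18 and 6. Both parts were low on chromosome 18 (-0.34 and -0.39) and chromosome 6 (-0.32 and -0.38), as a copy number change would give. The parts of chromosomes 2, 3, 5, 7, 8 and 13 had medians of opposite sign. Blocks of 40 genes 3 blocks apart had r = 0.207, and the highest of 1000 shuffles was 0.237. That extreme does not show how usual 0.207 is. Copy number of chromosomes or segments therefore cannot be told apart from other causes here. Of 1309 changed genes with a chromosome, 1129 stayed at least 1 log2 unit from 0 after the chromosome's median was subtracted.

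The 10 splits of the libraries in each comparison are too few for a share under 0.05. In each, 1 split, the real one, gave as many genes: 456 for PTH with 1 in the highest other split, 3005 for PF431396 with 0 and 1328 for the KO with 0.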
